A study of Mus musculus with 6 samples.

How the data were processed

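Total RNA of 6 mouse NK cell preparations was hybridised to Affymetrix arrays, with 3 arrays of IL-18 generated cells and 3 of unstimulated cells. Per the labels' protocols, cells were isolated on NK1.1, sorted by flow cytometry, and their RNA was purified on columns and labelled with biotin by the WT Terminal Labeling Kit for 1-colour hybridisation. The table used holds the authors' processed values for 28815 probe sets on all 6 arrays. The method of summarization and normalization and the log base are not given in the sources used here.

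The deposited values were treated as log2 expression, which was read from the values and is not stated by the authors. Each probe set was centred on its median over the 6 arrays, the largest departure of such a median from 0 being 5e-07, so the values are relative and hold no expression level. Values ran from -4.43 to 5.48, and the widest range within a probe set, 7.77, is too wide for log10 values from a 16-bit scanner. Rounding of the deposited numbers gave a further check. Within a tolerance of 0.15 of a step, 31.8% of probe sets lay on the grid of single-precision numbers between 8 and 16 on all arrays, where 3.1% would by chance, and 97.8% lay on the grid of numbers of at least 4, the range of log2 intensities. Natural logarithms of a 16-bit scanner's values allow a range of at most 3.09 on the grid above 8, yet 44 of the 239 probe sets with a wider range (18.4%) lay on it. Array medians over the genes tested lay between -0.025 and 0.039, so no further normalization was applied. For arrays, their number limits the precision, and no detection calls were used here.

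Probe sets were named from the platform's annotation table. Of the 28815, 21788 had 1 gene symbol, 1597 had several and 5430 were not listed, and only those with 1 symbol were used for genes. The identifiers of 21689 of them were found in the reference gene table, and 0 symbols needed an update. The 19943 genes tested were each represented by the mean of their probe sets, and 998 genes had more than 1. The plan had been to take the probe set with the highest mean, which centred values do not allow, and the mean, listed beforehand as an alternative, was used instead. For the same reason the planned filters on dim genes were not run. Genes in the lists were looked up by symbol or synonym, and 531 of 586 distinct list genes were measured.

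The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, no covariate, all 6 arrays), and p-values were adjusted over all genes by Benjamini-Hochberg. A gene was called at an adjusted p below 0.05 and an absolute log2 change of at least 1, while single members of the lists are said to rise or fall at an adjusted p below 0.05 alone. Gene lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, two-sided, with adjustment over the 31 lists, and with an estimated correlation, ranks and fry as alternatives. Genes of the sort were left out of the list tests. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

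The genes named follow a rule fixed before the data were examined. It took the genes of the sort, the 14 study genes, the 12 largest increases and 12 largest decreases among called genes whose groups did not overlap (without genes of the sort and provisional names), and, in each list, up to 2 members with the largest increase and 2 with the largest decrease that passed. Members given in addition to complete a count of 5 or fewer (Klrb1b, Klrc1, Btla, Ccr8, Cd44, Pmaip1, Il13 and Il23r) were chosen after their values were seen. The lists too were fixed beforehand.

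The procedure was tested on simulated data for the same contrast, with known changes set among 19943 genes. Calls at the adjusted p recovered 55.2% of 67 genes changed by a log2 of 0.5, 91.0% of 67 changed by 1 and 100% of 66 changed by 2, and 8 of the 172 genes called had not been changed. Of 5 lists shifted by 0.5, 5 were called, as were 2 of the other 26. Some of those 26 share genes with the shifted lists, so the 2 cannot be read as false calls. A gene in more than 1 shifted list was shifted by 0.5 for each of them. Genes were simulated independently of each other, whereas correlations estimated from the data reached 0.713 within a list. The simulation therefore does not show how often camera's preset correlation gives false list calls here. Alternatives covered limma's variance options, quantile normalization, centring of arrays, array weights, the fold threshold, all probe sets as features, the replicate number as a block, and leaving out each array in turn. The fit restricted to genes with 1 probe set was added after the data were seen. Probe sets without a symbol of their own were left out of the gene tests and counted separately.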

Results

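Gene expression was measured in mouse natural killer (NK) cells, innate lymphocytes that kill infected or transformed cells and secrete cytokines. Each of the 6 arrays held a separate cell preparation, with 3 preparations of IL-18 generated cells and 3 of unstimulated cells. Per the labels, NK1.1 isolated cells were kept overnight in medium with IL-2 at 300 IU and IL-18 at 25 ng/ml. IL-18 generated cells were then sorted by flow cytometry as CD11b negative and c-kit positive, and unstimulated cells as CD11b positive and c-kit negative, both within live NK1.1 positive, CD3 negative cells. Stimulus and sort gate therefore changed together. Whether the unstimulated cells were also cultured or received IL-2 is not given in the sources used here. The design text calls the preparations independent. The p-values below measure only the spread between these 6 arrays, whose number limits the precision. Every value is on a log2 scale relative to the median of its probe set over the 6 arrays, so changes can be read but expression levels cannot. A gene with a change near 0 may be undetected in both groups.

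The genes behind the sort served as a check of the labels and are no finding. Kit, which encodes c-kit, was higher in the IL-18 generated cells by 2.79 ± 0.13 (log2 change ± SE, n = 3 arrays per group, as for all changes below), or 6.90-fold. Itgam, which encodes CD11b, was lower, with a log2 change of -5.32 ± 0.11. Both followed the gates. Klrb1c, which encodes the NK1.1 antigen that was positive in both gates, was lower with a log2 change of -2.03 ± 0.11. The CD3 chain genes, negative at the surface in both gates, were higher, with log2 changes of 1.11 ± 0.14 for Cd3d, 1.26 ± 0.21 for Cd3e and 1.60 ± 0.20 for Cd3g. All of these passed limma's test with Benjamini-Hochberg adjustment, the weakest being Cd3e at an adjusted p of 0.000798.

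The comparison asks how the transcripts of NK cells generated with IL-18 differ from those of unstimulated NK cells. In the IL-18 generated cells, genes for amino acid supply and for building ribosomes rose together. Asns, which encodes asparagine synthetase, rose by 4.89 ± 0.11, and all 25 measured genes of ribosome biogenesis rose. Il2ra, the alpha chain of the IL-2 receptor, had the largest increase, 5.32 ± 0.11 or 40.0-fold. All 13 measured genes of mature NK cells fell, among them the lymphoid tissue egress receptor S1pr5 at -4.66 ± 0.11 and the inhibitory receptor Klrg1 at -4.10 ± 0.10. Markers of monocytes and neutrophils fell as well, and the lysozyme gene Lyz2 had the largest decrease of all, -7.16 ± 0.15. IL-18, the IL-2 and culture that came with it, and the sort gate cannot be told apart in any of these changes.

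Of the 19943 genes tested, 721 were higher and 647 lower in the IL-18 generated cells at a limma adjusted p below 0.05 and a change of at least 2-fold. Among them, 99 were higher and 184 lower by a log2 change of at least 2. The values of the IL-18 and unstimulated arrays did not overlap for 9696 genes, 48.6% of those tested, where chance gives 10%. The typical difference between arrays (root mean square over genes) was 0.16 to 0.23 within a group and 0.57 to 0.63 between groups. Counts depended on the fold threshold: the adjusted p alone called 3935 genes higher and 3332 lower, and limma's treat test against a log2 change of 1 called 313 higher and 328 lower. The groups did not overlap for any of the 115 genes named by rule, except Slamf6. The rule required this of the largest changes and took list members by adjusted p, so it is no further evidence of separation.

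The 12 largest increases, after Il2ra and Asns, included genes of cytokines and of TNF family ligands. Csf2, which encodes the growth factor GM-CSF, rose by 4.51 ± 0.17. Tnfsf4 (OX40 ligand) rose by 4.21 ± 0.08 and Tnfsf8 (CD30 ligand) by 3.63 ± 0.12. Amino acid transporters stood beside them, with Slc7a3 at 3.89 ± 0.15 and Slc7a5 at 3.71 ± 0.13, together with Mthfd2, a mitochondrial folate enzyme, at 3.51 ± 0.10. The semaphorin Sema6d rose by 4.75 ± 0.11, the ubiquitin ligase subunit Asb2 by 4.08 ± 0.16, the chromatin protein gene Utf1 by 4.04 ± 0.11 and the cell surface protease Adam8 by 3.98 ± 0.13. Limma adjusted p for these genes was at most 5.19e-08.

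Several of the 12 largest decreases were genes of myeloid cells or of immunoglobulins. Cybb, a subunit of the phagocyte oxidase, fell with a log2 change of -6.15 ± 0.19, and Ngp, a neutrophil granule gene, with -5.66 ± 0.32. Igsf6 and Treml4 changed by -5.24 ± 0.15 and -4.72 ± 0.19, and Pld4 by -4.60 ± 0.21. The adhesion molecule gene Ceacam1 fell with -5.39 ± 0.15 and Ace, angiotensin-converting enzyme, with -5.07 ± 0.13. A further 2 encode immunoglobulin kappa variable segments and fell with -5.18 ± 0.30 and -4.89 ± 0.52. Ly6a2, at -6.16 ± 0.19, belongs to a family of near-identical genes and its value is uncertain for that reason. The highest limma adjusted p among the 12 was 3.22e-05, for the latter kappa gene.

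**Figure D1:**
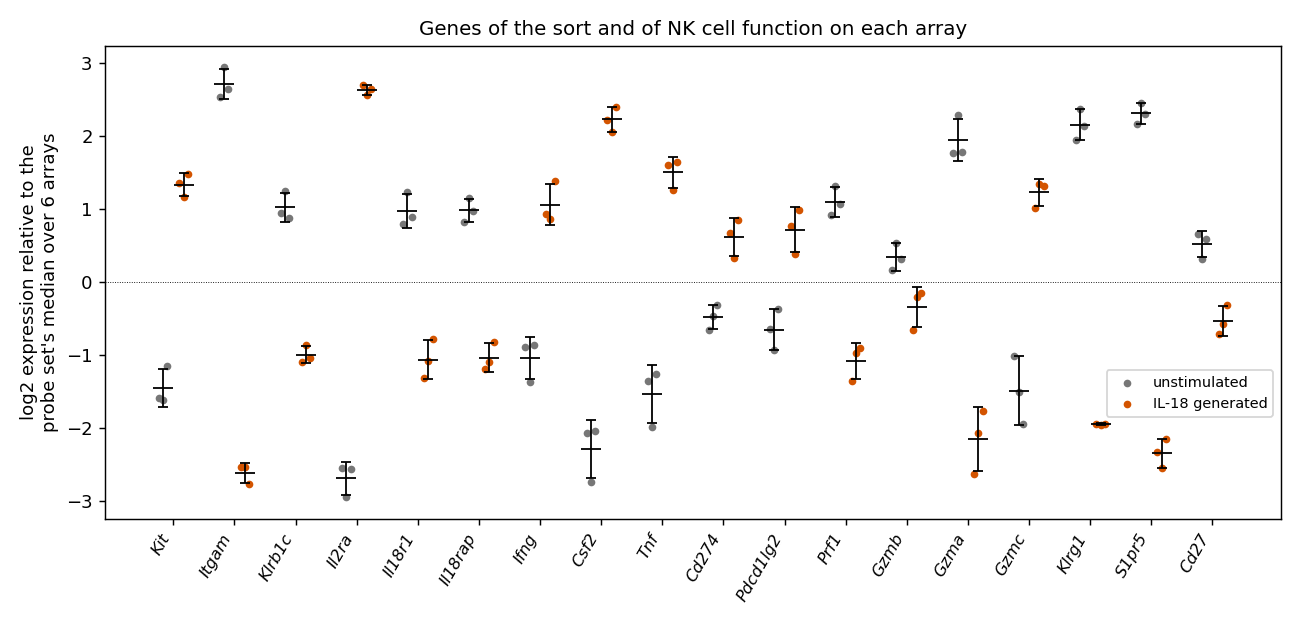
Log2 expression relative to each probe set's median over the 6 arrays (vertical axis) for genes of the sort and of NK cell function (horizontal axis), with 1 point per array and a bar at the mean ± SD of 3 arrays, unstimulated in grey and IL-18 generated in orange. Il2ra had a mean of 2.63 in the IL-18 generated cells and -2.69 in the unstimulated cells, and Itgam -2.62 and 2.70.

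Among 14 genes chosen beforehand for their part in IL-18 responses and in what is known of the study, 5 rose, 8 fell and 1 did not pass. Because the choice drew on knowledge of the study, its counts are no independent evidence of direction. Both chains of the IL-18 receptor fell, Il18r1 with a log2 change of -2.04 ± 0.14 and Il18rap with -2.02 ± 0.11, while Il2rb, the beta chain of the IL-2 receptor, fell by 0.40 on the log2 scale. The genes of the PD-1 ligands rose, Cd274 (B7-H1) 2.14-fold and Pdcd1lg2 by 1.37 ± 0.17, as did Ifng by 2.10 ± 0.16 and Tnfsf10 (TRAIL) by 0.61 ± 0.14. Unlike Tnfsf10, other genes of killing fell: Prf1 (perforin) with -2.17 ± 0.14, Fasl with -1.02 ± 0.14 and Gzmb (granzyme B) with -0.68 ± 0.14. Klrg1, from the list of mature NK genes, fell as given above. Cd27, from the list of immature NK genes, fell too, with -1.05 ± 0.12. Limma adjusted p for the 13 that passed was at most 0.00575. Il10 had a change of -0.22 ± 0.10 and did not pass, with a limma adjusted p of 0.102. Il10 passed without unstimulated replicate 2 (-0.28, adjusted p 0.0428) and with array weights (adjusted p 0.0366). Without unstimulated replicate 3 its change was -0.12 (adjusted p 0.337), and over its 13 alternatives the limma adjusted p ran from 0.0366 to 0.337. Counts adjusted over the list alone were 5 up and 9 down.

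Gene lists for NK cell biology, proliferation, metabolism and other cell types, fixed before the data were examined, were each set against all other genes with limma's camera test. Of 31 lists, 27 were called, 13 higher and 14 lower, at camera's preset correlation of 0.01 between genes. With the correlation estimated from the data, camera called 0 lists (9 had an unadjusted p below 0.05), so no list call holds under that setting, and each p is given beside its list. Fry, which asks whether a list's genes move on balance in a given direction without setting them against other genes, called 28 lists, and 31 in its test for changes in either direction.

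**Figure D2:**
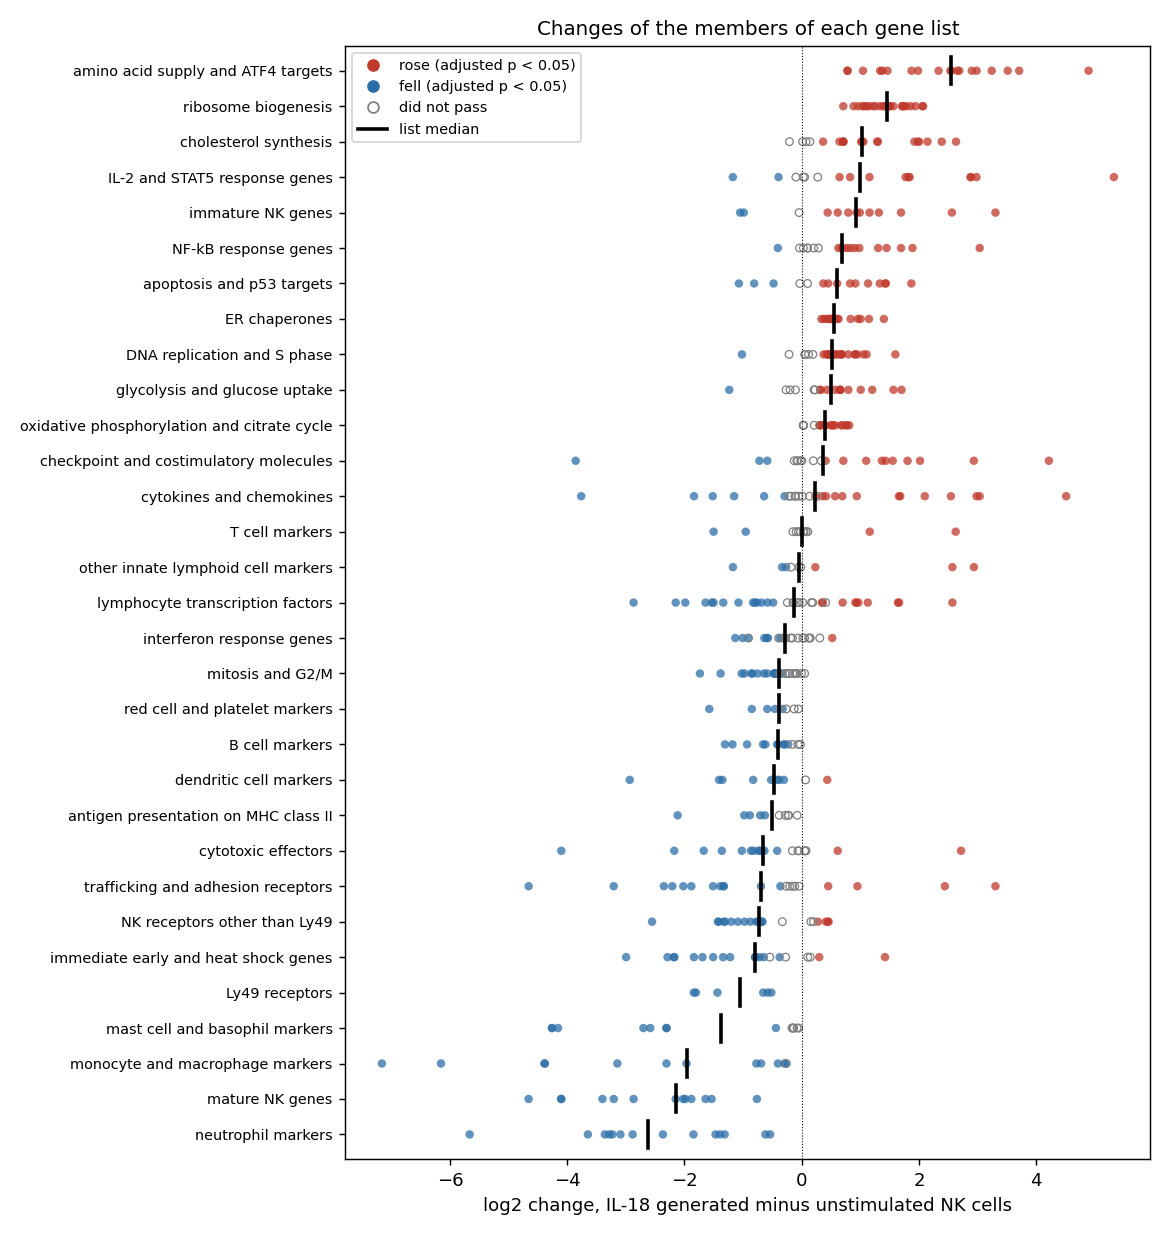
Log2 change of IL-18 generated minus unstimulated cells (horizontal axis) for each measured member of the 31 lists (vertical axis), with filled points for members that rose (red) or fell (blue) at adjusted p below 0.05, open points for the others, and a black bar at the list median. Medians ran from -2.63 for neutrophil markers to 2.54 for amino acid supply.

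The 13 measured genes of mature NK cells all fell, with a median of -2.15 (camera adjusted p 1.03e-13, and adjusted p = 0.154 with an estimated correlation). Besides S1pr5 and Klrg1, the list held transcription factor genes such as Klf2 at -2.87 ± 0.10 and Prdm1 at -2.15 ± 0.10. Of 13 immature NK genes, 10 rose, 2 fell and 1 did not pass, with a median of 0.93 (camera adjusted p 0.000312, and adjusted p = 0.224 with an estimated correlation). Cxcr6, a chemokine receptor, rose by 3.30 ± 0.13 and the phosphatase gene Inpp4b by 2.56 ± 0.17, whereas Cd27 and Cd7 fell, Cd7 with -0.99 ± 0.13. Both lists had the same counts when adjusted over the list alone. The gates set CD11b negative against CD11b positive cells, so neither list can separate IL-18 from the sort. Monocyte markers (median -1.96) and neutrophil markers (median -2.63) fell in the same arrays as the mature NK genes.

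Of 20 genes of cytotoxic effectors, 2 rose, 12 fell and 6 did not pass, with a median of -0.66 (camera adjusted p 0.0017, and adjusted p = 0.154 with an estimated correlation). Gzma (granzyme A) fell with a log2 change of -4.10 ± 0.20 beside Prf1, while Gzmc (granzyme C) rose by 2.72 ± 0.20 beside Tnfsf10. Granzymes C to G and N are close paralogs that can share probes, so their separate values are uncertain. Among 22 NK receptors other than the Ly49 family, 4 rose, 15 fell and 3 did not pass, with a median of -0.73 (camera adjusted p 0.000201, and adjusted p = 0.231 with an estimated correlation). Klrb1a fell with -2.55 ± 0.15, and Tyrobp, the signalling adaptor of activating receptors (DAP12), with -1.43 ± 0.08. Tyrobp is also expressed by myeloid cells, whose markers fell in the same arrays (medians of -1.96 for monocytes and -2.63 for neutrophils). The 4 that rose were the activating receptor gene Cd226 by 0.46 ± 0.09, Slamf6 by 0.45 ± 0.14, Klrb1b by 0.41 ± 0.09 and Klrc1 by 0.28 ± 0.08. Slamf6 had a limma adjusted p of 0.0281 and its groups overlapped. The call ended with array weights (limma adjusted p 0.0625) and without IL-18 replicate 1 or 3 (0.0803 and 0.102) or unstimulated replicate 2 or 3 (0.0747 and 0.0563), over a range of 0.00173 to 0.102 for 13 alternatives.

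Of the 21 Ly49 receptor genes, which encode receptors for MHC class I, 6 were measured and all 6 fell, with a median of -1.05 (camera adjusted p 0.000502, and adjusted p = 0.154 with an estimated correlation). Klra2 fell with -1.84 ± 0.13 and Klra3 with -1.80 ± 0.13. Ly49 genes are near-identical copies, so probes can read several of them and the values of single members are uncertain. Counts adjusted over the list alone were the same for the cytotoxic, NK receptor and Ly49 lists.

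Genes of secreted factors moved in both directions. Of 27 cytokine and chemokine genes, 13 rose, 6 fell and 8 did not pass, with a median of 0.23 (camera adjusted p 0.032, and adjusted p = 0.268 with an estimated correlation). Csf2 rose as given above and Tnf by 3.04 ± 0.18. The chemokine genes Ccl9 and Ccl4 fell with -3.76 ± 0.24 and -1.84 ± 0.19, in the same arrays in which monocyte markers fell (median -1.96). The list's call ended with quantile normalization (adjusted p 0.0579), on ranks (0.105) and without unstimulated replicate 2 (mean change 0.41, adjusted p 0.0512), and the highest adjusted p of the 12 alternatives other than the estimated correlation was 0.105. The lowest, 0.00391, came from fry, which does not set the list against other genes. Adjusted over the list alone, the counts were the same.

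Among 20 checkpoint and costimulatory molecules, 10 rose, 3 fell and 7 did not pass, with a median of 0.37 (camera adjusted p 0.00137, and adjusted p = 0.268 with an estimated correlation). The costimulator Icos rose by 2.94 ± 0.14 beside Tnfsf4. Entpd1 (CD39), which breaks down extracellular ATP, fell with -3.85 ± 0.15, Cd86 with -0.72 ± 0.10 and Btla with -0.59. Monocytes and macrophages also express Entpd1 and Cd86, and monocyte markers fell in the same arrays (median -1.96). Of 19 NF-kB response genes, 12 rose, 1 fell and 6 did not pass, with a median of 0.69 (camera adjusted p 5.26e-07, and adjusted p = 0.224 with an estimated correlation). Traf1 rose by 1.89 ± 0.08 beside Tnf, and the inhibitor gene Nfkbie fell with -0.41 ± 0.09. Of 16 IL-2 and STAT5 response genes, 10 rose, 2 fell and 4 did not pass, with a median of 0.99 (camera adjusted p 4.58e-06, and adjusted p = 0.154 with an estimated correlation). Lta, the lymphotoxin alpha gene, rose by 2.98 ± 0.17 beside Il2ra, and the cyclin gene Ccnd3 fell with -1.17 ± 0.08 beside Il2rb. IL-2 was part of the culture medium with IL-18, so neither this list nor any other isolates IL-18. In these lists 11 checkpoint and 13 NF-kB genes rose when adjusted over the list alone, and the other counts were the same.

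Cell cycle genes split between phases. Of 29 genes of DNA replication and S phase, 23 rose, 1 fell and 5 did not pass, with a median of 0.52 (camera adjusted p 4.67e-09, and adjusted p = 0.232 with an estimated correlation). Tipin, which guards replication forks, rose by 1.60 ± 0.18 and the primase gene Prim1 by 1.11 ± 0.09, while the repressor E2f8 fell with -1.02 ± 0.19. Of 29 genes of mitosis and G2/M, 0 rose, 17 fell and 12 did not pass, with a median of -0.38 (camera adjusted p 0.000172, and adjusted p = 0.439 with an estimated correlation). The cyclin gene Ccnb2 fell with -1.74 ± 0.15 and Mki67 with -1.38 ± 0.25. The IL-18 arrays were spread widely, with list means of -0.60, -0.03 and -0.32 in replicates 1, 2 and 3, against 0.22, 0.10 and 0.16 in the unstimulated ones. IL-18 replicate 2 lay nearest the unstimulated arrays. Fry did not call the mitosis list, with an adjusted p of 0.0508, and over the 12 alternatives other than the estimated correlation its adjusted p ran from 2.82e-08 to 0.0508. Of the S phase genes, 2 fell when adjusted over the list alone, and the other counts were the same.

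Genes of amino acid supply and targets of ATF4, the transcription factor of the amino acid response, made up the list with the highest median. All 19 measured members rose, with a median of 2.54 (camera adjusted p 1.82e-20, and adjusted p = 0.154 with an estimated correlation), Asns and Slc7a5 most. All 25 ribosome biogenesis genes rose too, with a median of 1.45 (camera adjusted p 1e-21, and adjusted p = 0.154 with an estimated correlation). Nop58 rose by 2.07 ± 0.12 and Tsr1 by 2.06 ± 0.08. The 16 genes of ER chaperones all rose, by less, with a median of 0.55 (camera adjusted p 2.6e-09, and adjusted p = 0.171 with an estimated correlation). Hyou1 rose by 1.40 ± 0.09 and Pdia6 by 1.15 ± 0.09. Counts adjusted over the list alone were the same for these 3 lists.

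Of 20 cholesterol synthesis genes, 16 rose, 0 fell and 4 did not pass, with a median of 1.02 (camera adjusted p 2.26e-11, and adjusted p = 0.154 with an estimated correlation). Idi1 rose by 2.63 ± 0.11 and the gene of the rate-limiting enzyme squalene epoxidase, Sqle, by 2.39 ± 0.09. Of 18 genes of glycolysis and glucose uptake, 12 rose, 1 fell and 5 did not pass, with a median of 0.50 (camera adjusted p 5.39e-05, and adjusted p = 0.231 with an estimated correlation). The kinase gene Pgk1 rose by 1.70 ± 0.08 and the lactate transporter gene Slc16a1 by 1.57 ± 0.14, while the glucose transporter gene Slc2a3 fell with -1.24 ± 0.11. Of 20 genes of oxidative phosphorylation and the citrate cycle, 15 rose, 0 fell and 5 did not pass, with a median of 0.40 (camera adjusted p 5.26e-07, and adjusted p = 0.224 with an estimated correlation). Cox5a rose by 0.81 ± 0.08 and Ndufs3 by 0.77 ± 0.08. Adjusted over the list alone, 1 cholesterol gene fell, 13 glycolysis genes rose and 16 oxidative genes rose, and the other counts were the same.

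Of 21 trafficking and adhesion receptors, 4 rose, 12 fell and 5 did not pass, with a median of -0.70 (camera adjusted p 0.000312, and adjusted p = 0.154 with an estimated correlation). Ccr7, the receptor for homing to lymph nodes, rose by 2.44 ± 0.12 beside Cxcr6, Ccr8 by 0.95 and Cd44 by 0.45. Cx3cr1 fell with -3.21 ± 0.11 beside S1pr5, and is also a monocyte receptor; monocyte markers fell in the same arrays (median -1.96). Among 33 lymphocyte transcription factors, 10 rose, 14 fell and 9 did not pass, with a median of -0.14, and camera did not call the list (adjusted p 0.274, and adjusted p = 0.56 with an estimated correlation). Rora rose by 2.57 ± 0.09 and Ahr by 1.66 ± 0.15, while Klf2 and Prdm1 fell as given above. Fry called this list lower with an adjusted p of 0.00239, and over the 12 alternatives other than the estimated correlation the adjusted p ran from 0.00239 to 0.388. Adjusted over the list alone, 11 of the transcription factors rose and 15 fell, and the trafficking counts were the same.

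Of 22 interferon response genes, 1 rose, 8 fell and 13 did not pass, with a median of -0.29, and camera did not call the list (adjusted p 0.0589, and adjusted p = 0.56 with an estimated correlation). Bst2 rose by 0.52 ± 0.10, and Cmpk2 and Oasl2 fell with -1.13 ± 0.13 and -1.01 ± 0.11. IL-18 replicate 3 stood apart, with a list mean of 0.22 against -0.28 and -0.49 in the other IL-18 arrays. Without it the list was called lower (mean change -0.50, adjusted p 0.00012), as it was without unstimulated replicate 1 (-0.32, adjusted p 0.0475) and with quantile normalization or median centring of the arrays (0.0361 and 0.0449). Without IL-18 replicate 2 the mean change was -0.14 (adjusted p 0.292), and over the 12 alternatives other than the estimated correlation the adjusted p ran from 0.00012 to 0.292. Of 15 apoptosis and p53 target genes, 10 rose, 3 fell and 2 did not pass, with a median of 0.60 (camera adjusted p 0.000553, and adjusted p = 0.224 with an estimated correlation). Phlda3 rose by 1.87 ± 0.17 and Aen by 1.43 ± 0.08. The survival gene Mcl1 fell with -1.07 ± 0.10, Trp53inp1 with -0.81 ± 0.12 and Pmaip1 with -0.48. Adjusted over the list alone, the counts of both lists were the same.

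Of 21 immediate early and heat shock genes, which respond within minutes to stimulation or handling, 2 rose, 15 fell and 4 did not pass, with a median of -0.79 (camera adjusted p 0.000312, and adjusted p = 0.382 with an estimated correlation). Atf3 rose by 1.42 ± 0.21, while Hspa1a fell with -2.99 ± 0.67 and Fos with -2.29 ± 0.51. The unstimulated arrays differed widely here, with list means of 1.08, 0.11 and 0.89 for replicates 1, 2 and 3 against -0.26, -0.31 and -0.23 in the IL-18 arrays. The calls of Hspa1a and Fos ended with limma's trended, robust variance (adjusted p 0.21 and 0.156). Without unstimulated replicate 1 they changed by -2.22 and -1.82, without unstimulated replicate 2 by -4.00 and -3.07, and over 13 alternatives their limma adjusted p ran from 4.68e-06 to 0.21 for Hspa1a and from 7.03e-07 to 0.156 for Fos. Klf6 rose by 0.30 ± 0.09, but its call ended without IL-18 replicate 1 (0.23, limma adjusted p 0.0981), without IL-18 replicate 3 (0.30, 0.0557) and without unstimulated replicate 1 (0.31, 0.0546), over a range of 0.0115 to 0.0981. In all, 16 fell when adjusted over the list alone.

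Markers of other blood cells were examined because a sort can retain such cells. Of the 84 measured members of the 7 lists, 33 were among the 647 genes lower by at least 2-fold and 2 among the 721 higher. Of 13 monocyte and macrophage markers, 0 rose, 12 fell and 1 did not pass, with a median of -1.96 (camera adjusted p 3.72e-08, and adjusted p = 0.224 with an estimated correlation), led by Lyz2 and Cybb. All 14 neutrophil markers fell, with a median of -2.63 (camera adjusted p 7.76e-08, and adjusted p = 0.226 with an estimated correlation), Ngp most, followed by the chemokine receptor Cxcr2 with -3.65 ± 0.31. Of 14 mast cell and basophil markers, 8 fell and 6 did not pass, with a median of -1.37 (camera adjusted p 0.000837, and adjusted p = 0.224 with an estimated correlation). The protease genes Cpa3 and Prss34 fell with -4.26 ± 0.76 and -4.26 ± 0.72. Of 10 dendritic cell markers, 1 rose, 8 fell and 1 did not pass, with a median of -0.47 (camera adjusted p 0.00333, and adjusted p = 0.231 with an estimated correlation). Zbtb46 rose by 0.44 ± 0.08, while Cd209a and Naaa fell with -2.93 ± 0.23 and -1.41 ± 0.11. All 13 monocyte markers fell when adjusted over the list alone, and the other counts were the same.

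Of 13 B cell markers, 0 rose, 10 fell and 3 did not pass, with a median of -0.40 (camera adjusted p 0.00162, and adjusted p = 0.232 with an estimated correlation), among them Bank1 with -1.31 ± 0.14 and Cd22 with -1.18 ± 0.13. Of 10 genes of antigen presentation on MHC class II, which B cells, dendritic cells and macrophages share, 0 rose, 5 fell and 5 did not pass, with a median of -0.51 (camera adjusted p 0.00523, and adjusted p = 0.321 with an estimated correlation). Ctss (cathepsin S) fell with -2.12 ± 0.20 and Cd74 with -0.98 ± 0.23, in the same arrays in which monocyte markers (median -1.96) and B cell markers fell. The class II list mean was 0.06 in unstimulated replicate 2, against 0.49 and 0.61 in unstimulated replicates 1 and 3. Of 8 red cell and platelet markers, 0 rose, 5 fell and 3 did not pass, with a median of -0.39 (camera adjusted p 0.00932, and adjusted p = 0.226 with an estimated correlation), Ppbp with -1.58 ± 0.20 and Itga2b with -0.85 ± 0.13. Adjusted over the list alone, 6 genes each fell in the class II and the red cell and platelet lists, and B cell counts were the same.

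Of 12 T cell markers, 2 rose, 2 fell and 8 did not pass, with a median of 0.00 and no camera call (adjusted p 0.858, and adjusted p = 0.926 with an estimated correlation). Camk4 and Trat1 rose by 2.63 ± 0.17 and 1.16 ± 0.14, and Lef1 and Ubash3a fell with -1.50 ± 0.12 and -0.96 ± 0.12. Of 9 markers of other innate lymphoid cells, 3 rose, 3 fell and 3 did not pass, without a camera call (adjusted p 0.624, and adjusted p = 0.639 with an estimated correlation). Their median was -0.05 while their mean was 0.41, and camera pointed up on statistics but down on ranks. Icos, Rora and Il13 rose, Il13 by 0.23, and Zbtb16, Il17rb and Il23r fell, with -1.17 ± 0.12, -0.33 ± 0.11 and -0.27. Fry called this list higher with an adjusted p of 0.000909, over a range of 0.000909 to 0.977 for the 12 alternatives other than the estimated correlation. The call of Il17rb ended without IL-18 replicate 2 or 3 (limma adjusted p 0.0978 and 0.0996) or unstimulated replicate 1 or 3 (0.0711 and 0.113), over a range of 0.00173 to 0.113 for 13 alternatives. Counts adjusted over the list alone were the same for both lists.

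**Figure D3:**
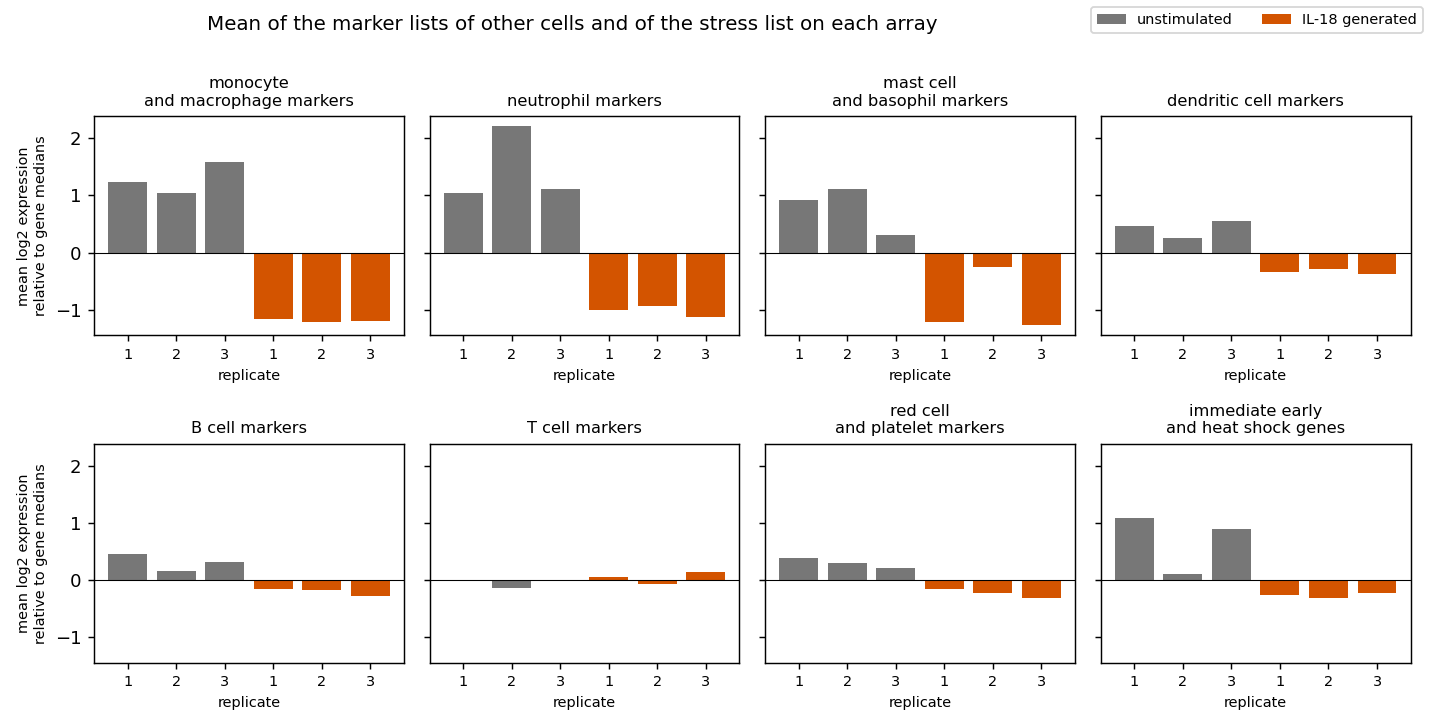
Mean log2 expression relative to the gene medians (vertical axis) of 7 lists of other blood cell markers and of the immediate early and heat shock list, with 1 bar per array for replicates 1 to 3 (horizontal axis), unstimulated in grey and IL-18 generated in orange. Neutrophil markers reached 2.21 in unstimulated replicate 2 against 1.04 and 1.12 in the other unstimulated arrays, and basophil markers stood at -0.25 in IL-18 replicate 2 against -1.22 and -1.27.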

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

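The tests of other cell types, of a stress response and of T cells given here were chosen only after the results were seen, while the splits of the arrays were planned.

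Among the 7027 probe sets that have several gene symbols or none listed, which the comparison of genes left out, 174 were higher and 135 lower in the IL-18 generated cells by at least 2-fold at a limma adjusted p below 0.05. Their largest changes were 3.47 and -6.03, a signal outside the genes reported on.

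The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 1368 genes and the highest of the others 0, so 1 of the 10 splits gave as many. For gene lists the real split called 27 and the highest of the others 20, and again 1 of the 10 splits gave as many. Each of the other splits called at least 11 lists with camera at its preset correlation, while limma called 0 genes and between 64 and 1303 genes had an unadjusted p below 0.05. These splits set 2 arrays of a group against 1 of it, so part of the real difference remains in them.

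Markers of monocytes, neutrophils and basophils were lower in the IL-18 generated cells, whose gate left out CD11b positive cells, while both gates required NK1.1. A lower share of NK cells would raise every other cell type alike. The median changes of neutrophil and monocyte markers that fell lay up to 1.76 apart over the 3 pairs of unstimulated arrays. Random lists gave a median of 0.19 and an upper bound of 0.56 for the same maximum. In that pair, replicate 2 minus replicate 3 (1 array each), the changes were 1.12 and -0.63 (95% bootstrap intervals over genes 0.64 to 1.48 and -0.78 to -0.38). Random lists, here and below, held genes drawn singly, whereas marker lists vary together (estimated correlations of 0.65 for neutrophils and 0.514 for monocytes). A difference between unstimulated arrays also does not show what lowered both lists between the groups. It therefore cannot decide on such a share as the only cause. Other cells in the unstimulated preparations may contribute: the members that fell had a median SD over the 3 unstimulated arrays of 0.35 for monocytes, 0.78 for neutrophils and 0.92 for basophils, above the upper bounds of the central 95% of random lists with like decreases (0.34, 0.39 and 0.49), though by little for monocytes. In these lists 11 of 12, 13 of 14 and 8 of 8 members peaked in the same array, replicate 3 for monocytes and replicate 2 for the others, with Lyz2 at 3.88 and S100a9 at 3.04 there, and 0 of their members belong to another list, while 2, 1 and 2 of them had values of at least 8 on all 6 arrays by the rounding check. A lower share of NK cells, as the only cause or as part of it, stays open. The neutrophil and the monocyte list mean both changed by -2.48 between the groups. The list means changed by -1.7 for basophils, -0.76 for dendritic cells and -0.51 for B cells. For red cells and platelets the change was -0.53, and for T cells 0.1. Members that may be undetected dilute a list mean, so these sizes cannot show whether the cell types moved alike. A decrease within NK cells, which the design ties to stimulus and gate, also stays open and was not tested.

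Immediate early and heat shock genes were lower in the IL-18 generated cells. Their list mean ranged by 0.98 over the unstimulated arrays and by 0.08 over the IL-18 arrays, and 13 of the 15 members that fell were lowest among unstimulated arrays in replicate 2, with Hspa1a at 3.99, 0.43 and 2.90 in replicates 1, 2 and 3. This is consistent with a stress response in part of the unstimulated preparations, a hypothesis found on the same data. The lowest unstimulated list mean, that of replicate 2, lay 0.34 above the highest IL-18 mean, and whether such a response accounts for the whole difference stays open. Culture or stimulus, confounded with the groups, stays open and was not tested.

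Cd3d, Cd3e and Cd3g were higher in the IL-18 generated cells although both gates required CD3 negative cells. The other T cell markers had an upper quartile of log2 change of 0.08, below the smallest change of the CD3 chains, 1.11. This cannot decide whether T cells were in the IL-18 sort, as most of these markers may be undetected. Cd28 at 0.03, Ubash3a at -0.96 and Lef1 at -1.50 had values of at least 8 on all arrays by the rounding check and did not rise. Most other markers did not have such values, and 2 markers, Camk4 and Trat1, rose by 2.63 and 1.16. T cells in the sort stay open, as does a difference in transcription of the CD3 chains within the sorted NK cells, which was not tested.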

How the results depend on the processing

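The fit of genes with 1 probe set was chosen after the data were seen, and all other alternatives were planned. The choice of fold threshold moved the counts of 721 genes higher and 647 lower by over 1.5 times. The adjusted p alone gave 3935 and 3332, and treat against a log2 change of 1 gave 313 and 328, by construction. Camera with an estimated correlation called 0 of the 27 lists. A correlation above the preset 0.01 cannot be the cause for every list. For cytotoxic effectors and trafficking receptors the estimates were -0.031 and -0.017. Their camera adjusted p still rose from 0.0017 and 0.000312 to 0.154. Before adjustment, their camera p at the preset was 0.00126 and 0.000171, while the lowest of any list with an estimated correlation was 0.0146. For them the rise therefore came neither from a higher correlation nor from the adjustment alone. The other called lists had estimates above the preset. How much of their rise came from the correlation was not tested, so a lost call under that setting does not measure it. Under the other settings, 663 to 985 genes were higher, 620 to 805 lower and 26 to 31 lists called, the highest gene counts with all probe sets as features. Over 12 other fits at gene level, 1270 to 1368 of the 1368 called genes were shared. Without unstimulated replicate 2, whose array weight of 0.46 was the lowest, 764 genes were higher and 628 lower. The replicate block gave 723 higher, 648 lower and 28 lists, adding the interferon list (adjusted p 0.0228) and changing no other list or named gene call. The replicate numbers did not clearly pair the arrays, judged by correlations of each array's deviations from its group mean. These were 0.238, 0.007 and -0.02 for same-numbered arrays, and the highest was 0.248, for IL-18 replicate 3 with unstimulated replicate 2. For the 115 named genes, 1473 of 1489 alternative values kept direction and call, 14 lost the call, 2 gained it and 0 reversed. For lists, 365 of 403 kept both, 31 lost the call (27 of them with an estimated correlation), 7 gained it and 0 reversed. Filters on dim genes were not run, because the centred values hold no level, and signal over background could not be judged.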

Other observations

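The lists and genes in this part, and all tests of them, were chosen only after the values were seen. Their p-values are therefore no independent evidence of a shift and cannot be compared with those of the 31 lists fixed beforehand. Genes that charge transfer RNA with amino acids rose together in the IL-18 generated cells. All 17 measured cytosolic aminoacyl-tRNA synthetases rose, with a median log2 change of 1.44 (camera adjusted p 3.77e-15, and adjusted p = 0.091 with an estimated correlation), among them Gars by 2.03 ± 0.09 and Iars by 1.99 ± 0.07 (SE, n = 3 arrays per group). Of 16 mitochondrial synthetases, 11 rose, 0 fell and 5 did not pass, with a median of 0.42 (camera adjusted p 2.63e-06, and adjusted p = 0.129 with an estimated correlation), Nars2 by 1.12 ± 0.08. Of 33 genes of mitochondrial protein import and mitochondrial chaperones, 26 rose, 1 fell and 6 did not pass, with a median of 0.82 (camera adjusted p 9.64e-14, and adjusted p = 0.0839 with an estimated correlation). The chaperone genes Hspa9 and Hspd1 rose by 2.41 ± 0.08 and 2.13 ± 0.11, the protease gene Lonp1 by 1.96 ± 0.14, and Tomm34 fell with -0.36 ± 0.08.

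Among 41 ligands and receptors of the TNF superfamily, 18 rose, 9 fell and 14 did not pass, with a median of 0.20 (camera adjusted p 0.000801, and adjusted p = 0.213 with an estimated correlation). Beside Tnfsf4 and Tnfsf8, Tnfrsf8, the receptor for the Tnfsf8 ligand (CD30), rose by 2.76 ± 0.09, the decoy receptor gene Tnfrsf11b by 2.59 ± 0.15, Tnfrsf10b, the receptor for TRAIL, by 2.41 ± 0.10 and Tnfrsf25 by 2.09 ± 0.11. Tnfrsf1a, a receptor for TNF, fell with -1.07 ± 0.08. Of 22 ATP-binding transporters of the A and G families, many of which move lipids, 1 rose, 9 fell and 12 did not pass, with a median of -0.20 (camera adjusted p 0.00162, and adjusted p = 0.0839 with an estimated correlation). The cholesterol exporters Abca1 and Abcg1 fell with -2.89 ± 0.11 and -2.15 ± 0.18, and Abca5 rose by 0.57 ± 0.09. Macrophages also express Abca1 and Abcg1, and monocyte markers fell in the same arrays (median -1.96).

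Single arrays differed in immunoglobulin genes and basophil genes. Of 13 measured immunoglobulin and Jchain genes, 11 fell by at least 2-fold, and all 11 were highest in unstimulated replicate 1. Their mean there was 3.61, against 1.03 and 1.85 in unstimulated replicates 2 and 3. B cell markers had the same order in these arrays, with list means of 0.45, 0.16 and 0.31 in replicates 1, 2 and 3. The basophil genes Cpa3, Prss34, Mcpt8, Fcer1a and Ms4a2 had a mean of -0.41 in IL-18 replicate 2, against -2.99 and -2.97 in IL-18 replicates 1 and 3, and all 5 were highest among the IL-18 arrays in replicate 2.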
